A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

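The experiment compared leaf blades of rice (Oryza sativa Japonica, cultivar Hinohikari) treated with 10 µM linalool, a volatile monoterpene alcohol, for 1 day with control blades. The tissue was the fifth-leaf blade of plants grown at 25 ºC. Each group held 4 replicates, which the design text calls biological, and each replicate pooled at least 3 plants. The labels disagree on the control, which the descriptions call mock-treated and the source names call untreated. It is called mock here.

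Per the labels' protocols, RNA was extracted with Trizol, 100 ng was labelled with Cy3 as a single colour, and the arrays were hybridised for 17 h at 65 ºC. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, and the deposited intensity values are its processed signal, corrected for background on a linear scale and not scaled between arrays. The deposited series matrix held the same intensity values multiplied by 1 constant per array, between 1.37 and 2.51. The rule behind these constants is not given in the sources used here. Its column medians ran from 298.9 to 339.8.

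The processed signal was taken to log2 and each array's 75th percentile over the non-control spots was subtracted. Spots that the software marked as non-uniform were left out, 4 to 17 per array, and spots of 1 probe were averaged. No spot was saturated. Of 42477 probes, 33120 were well above background on at least 4 of the 8 arrays and were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, adjusted p below 0.05). A second count required a 2-fold difference. A gene was represented by its tested probe with the highest mean over all arrays, which gave 21544 genes. The 1358 probes whose name columns point to different loci were left out of gene-level work. Where a probe was not well above background on any array of a group, its fold is a bound, written as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

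The array files give locus identifiers and transcript accessions but no gene symbols or product descriptions. None of the 1051 RefSeq accessions on the array was found in the reference table for assembly ASM3414082v1, so no coordinates are given. Symbols and list memberships therefore come from general knowledge of published rice locus names and were not read from a file. They were tested against the reference, which holds symbols with positions but no locus identifiers of this kind. Of 311 recalled names, 145 were unique in the reference, on the chromosome in the locus identifier and in the order of locus numbers. Another 3 were out of order, 17 pointed to another chromosome, 21 matched several genes and 125 were not found. A symbol is printed only if it is among the 145 or belongs to the 7 genes named in the fixed design.

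The rule for named genes was fixed before the data were examined: the 12 largest rises and falls with no overlap between groups, up to 4 members with the smallest p of each list with a call or with at least 2 changed members, and 7 genes reported whatever their values. Here up to 3 members with a printable symbol are taken for each called or previously fixed list and 1 for each other list. The result for 1 gene that this rule names is not reported here. The members of 7 lists were fixed in advance. The other 29 lists had been planned as keyword searches or were added, and their members were chosen after the files were opened but before any signal of a listed gene was read. Planned lists of cytochromes P450, glycosyltransferases, ABC transporters, receptor-like kinases, NB-LRR proteins, cytosolic ribosomal proteins, epidermal wax genes, auxin genes and calcium genes were not built, and of the ERF factors only the DREB1 group was. Lists with at least 4 tested genes, 33 in all, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. For these list tests, a value missing through a flagged spot was filled with its group's mean.

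All mock arrays lay on 1 slide and all linalool arrays on another, so slide and treatment cannot be told apart. On simulated data for this comparison with 33079 probes limma recovered 87.9% of changes of 2 on the log2 scale, 65.7% of changes of 1 and 11.9% of changes of 0.5, with 6 false calls. Only 66 or 67 probes were changed per size, against 22304 that passed in the data. The adjustment is stricter when few probes change, so these rates need not hold for the real comparison. In a simulation over 21544 genes in which only the photosystem list was lowered by 1, camera called that list and 0 of the others. In the data 14540 genes passed, and the estimated correlation within a list reached 0.95. The simulated result therefore need not hold for the real lists. Alternatives in normalisation, values, filtering, test and replicates were run. The number of arrays limits the precision.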

Results

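Gene expression was measured on 8 single-colour arrays, 4 of mock and 4 of linalool-treated rice leaf blades, each from a pool of at least 3 plants. The 75th percentile of the processed signal was 849.6 to 999.6 on the mock arrays and 1092 to 1605 on the linalool arrays. Between 73.3% and 77.3% of spots were well above background on each array. Across 33079 probes, arrays correlated at 0.975 to 0.992 within the mock group and at 0.987 to 0.996 within the linalool group, against 0.866 to 0.905 between groups.

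The comparison asks which rice genes respond to 1 day of 10 µM linalool. How much of the measured transcriptome differed depended on the processing. With limma, 22304 of 33120 probes passed an adjusted p of 0.05, of which 9405 were higher and 12899 lower after linalool. At least 2-fold differences were found for 9869 probes, 3822 higher and 6047 lower. Counted by gene, 14540 of 21544 changed, 6245 upwards and 8295 downwards. With normexp correction, 9364 probes and 5723 genes passed, which is no longer most of those tested, and 50.6% of these probes were higher. The linalool values all lay on one side of the mock values for 63.4% of genes, against 2.86% expected by chance. A further view is given by detection: 527 probes were well above background on all linalool arrays and no mock array, and 399 showed the opposite. These directions are relative to the 75th percentile. Scaled to the 6 measured spike-in probes, a choice made after seeing the data, the median of all genes moved up by 0.79 on the log2 scale, and 19632 probes were higher and 4375 lower. Slide and treatment coincide in this design, so a difference between the slides or between batches of plants cannot be told apart from the treatment.

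Many pathogenesis-related (PR) genes rose. Of 11 tested members of the PR list, 7 rose, 3 fell and 1 did not pass, and 11 passed when adjusted over the list alone. The median difference was 5.23, but the list was not called by camera (adjusted p = 0.078). It was called with normexp correction and without mock replicate 2. That array had the highest mock level for 7 of the 11 genes, for example -4.26 against -8.85 to -8.43 for Os11g0592000 and -1.58 against -7.22 to -5.49 for Os12g0555000, and linalool replicate 1 had the highest linalool level for 10. PBZ1 (Os12g0555500), a PR-10 protein gene, rose from -0.86 ± 0.73 to 7.79 ± 0.29 (SD, n = 4 each, log2 level relative to the 75th percentile), a difference of 8.65 with a limma adjusted p of 6.08e-07. The neighbouring list member Os12g0555000 had the largest measured difference among rising genes, 11.14 on the log2 scale, although only 2 of its mock arrays were well above background and the mock values had an SD of 2.60. By locus number, Os12g0555000, Os12g0555200 and Os12g0555500 lie close together among the 7 risers, as do Os11g0592000 and Os11g0592200. Such neighbours may be read by the same probes, so the risers may not be independent. PR1b (Os01g0382000) fell by 1.24 (limma adjusted p = 0.000225). PR1a (Os07g0129200) was not well above background on any array. None of the other genes among the 12 largest rises carries a symbol here, and examples are Os07g0418500 (11.04) and Os09g0444900 (at least 1647-fold). None of the 12 largest falls has one either, and examples are Os03g0843800 (at least 1969-fold lower) and Os06g0306300 (at least 257.7-fold lower). These genes were ranked by measured differences, and the lower group was not well above background on any array for 6 of the 12 rises and 9 of the 12 falls, so their order is uncertain.

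Genes for photosynthesis fell. Of 26 photosystem and light-harvesting genes, 25 fell and 0 rose, with a median of -2.03 (camera adjusted p = 6.12e-08). All 11 carbon fixation genes fell (median -2.46, camera adjusted p = 0.00129), as did all 6 chlorophyll synthesis genes (median -1.91, camera adjusted p = 0.0188). With an estimated correlation these calls were lost, with adjusted p = 0.72, 0.73 and 0.72. Arrays within a group also differed on these genes. Mock replicate 2 had the highest mock level for 22 of the 26 photosystem genes, and the highest linalool level was on replicate 1 for 11 of them and on replicate 2 for the other 15, and never on replicates 3 or 4 for any gene of the 3 lists. All 3 lists were still called without linalool replicates 1 and 2 and without 3 and 4. PsaH (Os05g0560000), a photosystem I subunit gene, fell by 1.97 from 7.74 ± 0.19 to 5.77 ± 0.30 (SD, n = 4 each). RCA (Os11g0707000), encoding Rubisco activase, fell by 2.07 from 9.03 ± 0.10 to 6.96 ± 0.43. Among chlorophyll synthesis genes, CHLH (Os03g0323200) fell by 2.86, CHLI (Os03g0563300) by 2.27 and PORA (Os04g0678700) by 5.45. Symbols were borne out by the reference for 1 of the photosystem genes, 1 of the carbon fixation genes and 5 of the chlorophyll synthesis genes, and the other members rest on recalled names. With only borne-out members, the photosystem and carbon fixation lists were too small to test, and the camera p for chlorophyll synthesis was 0.0088, or 0.075 when adjusted over the 17 lists that could still be tested.

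**Figure D1:**
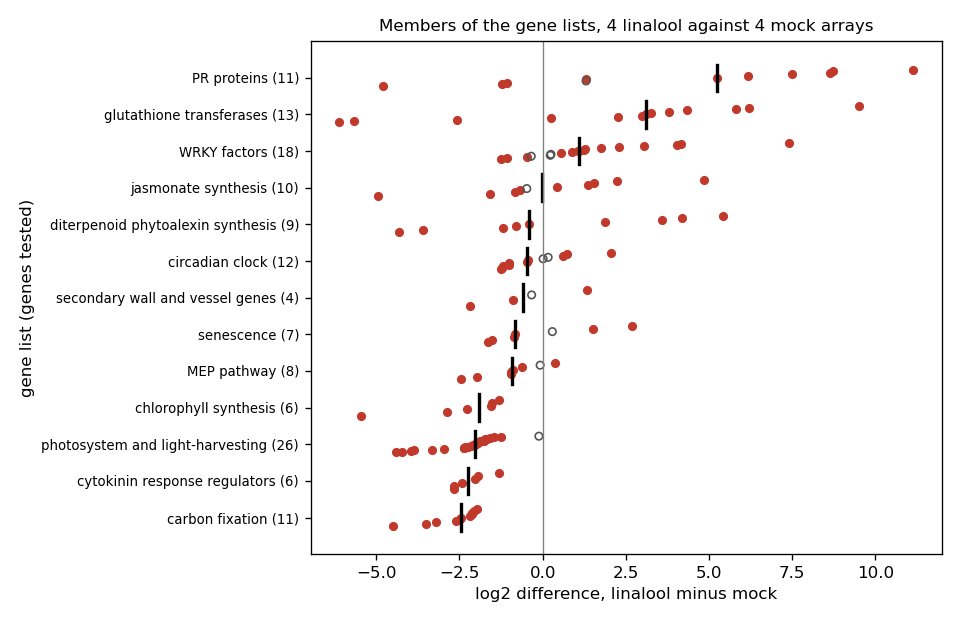
Log2 difference between linalool and mock (horizontal axis) for each tested member of the 7 lists fixed in advance and the 6 lists called by camera. Filled points passed a limma adjusted p of 0.05, open points did not, and black bars are list medians, which run from -2.46 for carbon fixation to 5.23 for PR proteins.

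The other called lists were WRKY transcription factors, glutathione transferases and cytokinin response regulators. Of 18 WRKY genes, 12 rose and 3 fell (median 1.08, camera adjusted p = 0.0188, and adjusted p = 0.72 with an estimated correlation). Symbols were borne out for 5 of them, and with these alone the camera adjusted p was 0.48. WRKY45 (Os05g0322900), a regulator of defence, rose by 2.30 (limma adjusted p = 0.00822), although its groups overlapped, with mock replicate 1 at -1.64 against -3.96 to -3.25 on the other mock arrays. WRKY62 (Os09g0417800) was at least 9.49-fold higher. The probes of WRKY76 (Os09g0417600) disagreed, with 2 higher and 2 lower. Its brightest probe had a log2 difference of -1.25, and the mean over its probes one of 0.66. Of 13 glutathione transferase genes, 10 rose and 3 fell (median 3.097, camera adjusted p = 0.0188, and adjusted p = 0.72 with an estimated correlation). The call was also lost with quantile normalisation, and none of the symbols was borne out. Members of such tandem families are near-identical in places, so their single values are uncertain. All 6 cytokinin response regulators fell (median -2.23, camera adjusted p = 0.0245, and adjusted p = 0.72 with an estimated correlation), among them RR1 (Os04g0442300) by 2.66, RR2 (Os02g0557800) by 1.94 and RR4 (Os01g0952500) by 1.32. With only probes above background on all arrays, the calls of the WRKY, glutathione transferase and cytokinin lists were lost.

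Terpenoid genes moved in both directions. Of 9 diterpenoid phytoalexin genes, 4 rose and 5 fell (camera adjusted p = 0.69), and 9 passed when adjusted over the list alone. CYP71Z7 (Os02g0570700) and CPS2 (Os02g0571100) were at least 17.9-fold and 7.78-fold higher, and CYP701A8 (Os06g0569500) at least 10.96-fold lower. In the plastidic MEP pathway, which makes isoprenoid precursors, 6 of 8 genes fell and 1 rose (median -0.92, camera adjusted p = 0.12, but called with normexp correction), and 7 passed when adjusted over the list alone. DXR (Os01g0106900) fell by 1.99. Linalool synthase (Os02g0121700) was well above background on 3 linalool arrays and 0 mock arrays and was not tested. Its level was -7.49 ± 1.03 in mock and -6.88 ± 0.61 after linalool.

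Of 10 jasmonate synthesis genes, 5 rose and 4 fell (camera adjusted p = 0.77), and 9 passed when adjusted over the list alone. The largest rise in this list was 4.86, for Os08g0509100, which was well above background on only 1 mock array. AOS2 (Os03g0225900), encoding an allene oxide synthase, was at least 15.03-fold lower. JAR1 (Os05g0586200) fell by 0.83, and AOC (Os03g0438100) had a difference of -0.68 that was 0.11 when scaled to the spike-in probes. AOS1 (Os03g0767000) did not pass (-0.48, limma adjusted p = 0.0796), and neither did NPR1 (Os01g0194300), the salicylate co-activator (0.22, limma adjusted p = 0.19). Among 12 clock genes, 3 rose and 7 fell (camera adjusted p = 0.61), and 10 passed when adjusted over the list alone, and LHY (Os08g0157600), PRR37 (Os07g0695100) and ELF3 (Os06g0142600) had log2 differences of -1.19, -1.24 and -0.998. In the senescence list, 2 of 7 genes rose and 4 fell, and 6 passed when adjusted over the list alone. SGR (Os09g0532000), which acts in chlorophyll breakdown, rose by 2.68, and NYC1 (Os01g0227100) had a difference of -0.84. Of 4 secondary wall genes, 1 rose and 2 fell, and 3 passed when adjusted over the list alone. Of 6 dividing-cell genes, 2 rose and 2 fell.

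**Figure D2:**
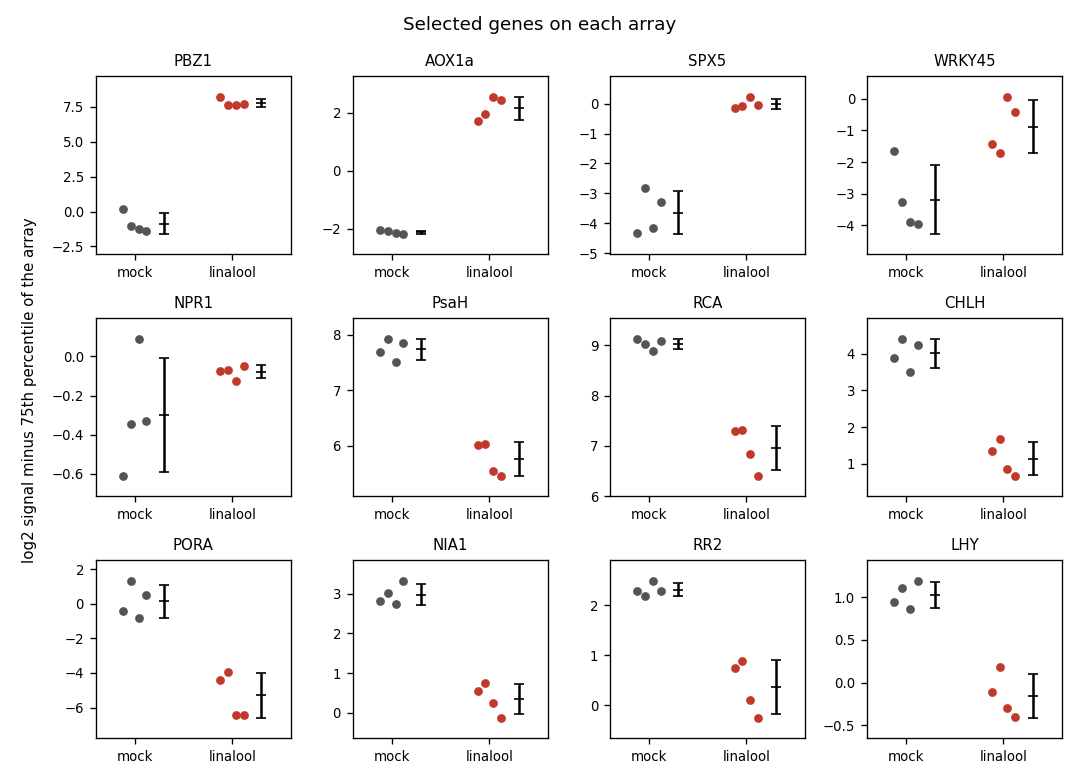
Log2 signal relative to the array's 75th percentile (vertical axes, which differ between panels) on each of 4 mock (grey) and 4 linalool (red) arrays for 12 named genes, with the mean ± SD beside the points. PBZ1 lies near -0.86 in mock and 7.79 after linalool, whereas the NPR1 values overlap.

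Single members of other lists also moved. AOX1a (Os04g0600200), encoding alternative oxidase, rose by 4.28 (limma adjusted p = 8.54e-07), while 5 of 11 antioxidant genes rose and 5 fell. SPX5 (Os03g0406100), a phosphate-signalling gene, rose by 3.64, in a list where 6 of 9 genes rose and 0 fell. NIA1 (Os08g0468100), a nitrate reductase gene, fell by 2.62, and EXPA2 (Os01g0823100), an expansin gene, was at least 64.1-fold lower. SWEET13 (Os12g0476200), a sugar transporter gene, rose by 3.20, in a list where 2 of 3 genes rose and 1 fell. Cht3 (Os06g0726100) rose by 3.91, while 7 of 17 chitinase and glucanase genes rose and 6 fell. Only 2 of the mock arrays were well above background for Cht3, and its mock values had an SD of 1.25, so its difference is uncertain. The actin gene ACT1 (Os03g0718100), often used as a reference, rose by 0.78, the most in a list of 5 reference genes. Of these, 2 rose and 3 did not pass, with a median of 0.11. With normexp background correction of the median signals and an offset of 50, PR1b, CYP71Z7, CPS2, CYP701A8, AOS2, WRKY62, EXPA2 and RR1 no longer passed. Scaled to the spike-in probes, PR1b, JAR1, LHY, PRR37, ELF3 and NYC1 no longer passed.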

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

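The spike-in, scaling, cell-share and clock tests below were chosen after the results were seen. Of 100 groups of 4 arrays tested for an array far from the others, 8 stood out, where chance gives about 5. Linalool replicate 1 had a PBZ1 level of 8.22 against 7.61 to 7.68 on the other arrays, and a JAR1 level of 0.45 against 0.56 to 0.57. Linalool replicate 4 had a CYP701A8 level of -8.85 against -7.63 to -7.42, and an ABA8ox2 (Os08g0472800) level of -4.55 against -3.88 to -3.79. Linalool replicate 3 had a Cht3 level of -3.21 against -2.96 to -2.95. Mock replicate 4 had a NAC5 (Os11g0184900) level of 3.92 against 4.06 to 4.07. Mock replicate 1 had an AOS1 level of -1.24 against -2.11 to -2.00. The 75th percentile of mock replicate 4 was 999.6 against 849.6 to 870.9.

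The first pattern weighed is the breadth of the difference. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many probes as the real 22304, namely the real split, and the highest of the others gave 0. A share of 1 in 35 is the smallest this test can give, so it argues against chance but cannot exclude it. The other splits mix the groups, so any large gap between the groups, whatever its source, lowers their counts. A different intensity curve on the 2 slides is argued against by quantile normalisation, which left 21933 probes. Labelling or scanning that differed as a whole is argued against, for brighter signals, by the spike-in probes. Their median absolute difference between slides was 0.047 on the log2 scale before scaling, although 1 of the 6, the dimmest, differed by -0.66. The median background also differed, at 26 to 28 on the mock arrays and 19 on every linalool array. A difference between the slides at low signal therefore stays open. Artefacts of single probes are argued against where a gene had another tested probe: of 1710 such genes whose first probe changed at least 2-fold, 99.2% had a second probe with the same direction. A different batch of plants, harvest or RNA stays open, since 0 slides hold both groups and it cannot be told apart from an effect of linalool.

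The second pattern is the fall of photosynthesis genes, with a median of -2.13 over 43 genes. Compression of bright probes is argued against by 234 other genes matched on brightness, whose median was -0.22, and the choice of scaling by a median of -1.34 when scaled to the spike-in probes. A lower share of mesophyll cells stays open, since the lower of the medians of the dividing-cell and secondary wall lists was -0.60 with members going both ways. Harvest at another time of day also stays open. Of the clock genes, 8 differed by more than 0.5. The evening gene PRR1 (Os02g0618200) did not pass, however (0.16, limma adjusted p = 0.36), and so did not oppose LHY. Other list members did: 3 of 12 clock genes rose and 7 fell, LHY among the latter. Os01g0971800 rose most, by 2.05 (limma adjusted p = 3.04e-06). Both groups were sampled after 24 h, and the clock hour is not given in the sources used here. An effect of linalool is a candidate explanation that these data cannot separate from these.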

How the results depend on the processing

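The spike-in scaling, the pairs of left-out arrays and the restriction to tested symbols were chosen after seeing the data. Normexp correction, run on median signals as the files hold no mean signal, moved the counts to 9364 probes, 4723 probes of at least 2-fold and 5723 genes, and called 9 lists, adding PR proteins, the MEP pathway and phosphate starvation. Signal, background correction and offset change together here, and the cause was not tested. Without 1 replicate at a time, the counts ran from 20501 to 22445 probes, 9468 to 10305 probes of at least 2-fold, 13406 to 14609 genes and 6 to 8 lists, the 8 without mock replicate 2, when PR proteins and phosphate starvation were called too. With only probes above background on all arrays, 3 lists were called, without WRKY, glutathione transferases and cytokinin. Quantile normalisation called 5, without the glutathione transferases, and no filter called 7, adding phosphate starvation. With an estimated correlation 0 were called. Fry, which does not compare a list with other genes, called 27 of 33 lists, including these 6. With only borne-out members, 17 lists could be tested and 0 were called, with camera adjusted p of 0.075 for both chlorophyll synthesis and cytokinin response regulators. All 6 cytokinin genes are borne out, and their adjusted p rose only as lists with smaller p left or weakened. The photosystem, carbon fixation and glutathione transferase lists were too small. The remaining planned settings kept each count within 1.5 times its value. Spike-in scaling raised the share of higher probes from 42.2% to 81.8%, and of higher genes from 43.0% to 82.9%. It no longer called the WRKY and glutathione transferase lists, but called the wall loosening list. The median of all genes moved by 0.13 with normexp, 0.12 with quantile normalisation, -0.19 with no filter and 0.79 with spike-in scaling. WRKY76 turned to 0.66 with the mean of its probes, and AOC and SLR1 (Os03g0707600) to 0.11 and 0.080 with spike-in scaling. The latter follow from the 0.79, and 2 probes of WRKY76 were higher and 2 lower. The linalool arrays fell into pairs: deviations from the group mean correlated at 0.33 between replicates 1 and 2 and at 0.46 between 3 and 4. Across these pairs they correlated at -0.73 to -0.66. Deviations from the mean of the same 4 arrays tend to correlate negatively by construction. Those of the mock arrays did so throughout, at -0.62 to -0.10. Limma treated the 4 arrays as independent, and the cause of the pairs was not tested. Leaving out linalool replicates 1 and 2 together gave 20596 probes, and 3 and 4 together 18535. Replicate numbers do not pair the samples, as deviations of same-numbered arrays correlated at -0.003, 0.17, 0.11 and -0.11, and the replicate block gave 21245 probes, 9873 of at least 2-fold, 13848 genes and 6 lists. Slide as a fixed or random block and scan date as a block were not run, since each slide and scan batch holds 1 group.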

Other observations

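Among list members outside the groups above, ACS1 (Os03g0727600), an ethylene synthesis gene, fell by 2.17 in a list where 6 of 8 genes fell and 1 rose. Hd1 (Os06g0275000), a flowering regulator, rose by 2.30, in a list where 1 of 4 genes rose and 3 fell. RAB16D (Os11g0453900), a dehydrin gene, was at least 4.15-fold higher, in a list where 2 of 6 genes rose and 2 fell. HSFA2d (Os03g0161900), a heat stress factor gene, fell by 2.51, while 8 of 21 heat shock genes rose and 4 fell. Single arrays stood apart on this list: mock replicate 1 was the highest mock array for 16 of the 21 genes, for example 7.11 against 3.59 to 3.97 for Os01g0184100, and linalool replicate 3 the highest linalool array for 16. Of 5 DREB1 factor genes, 1 rose and 2 fell, and mock replicate 1 was the highest mock array for all 5. With normexp correction, ACS1, Hd1 and RAB16D no longer passed. Of the 510 microRNA probes on the array, 211 were tested, and 14 were higher and 142 lower after linalool, so 67.3% were lower against 38.9% of all tested probes. Scaled to the spike-in probes, 59 were higher and 71 lower, so 33.6% were lower against 13.2% of all tested probes. The microRNA probes were not matched on brightness to the others, and whether they read mature microRNAs was not tested. Without the filter on dim probes, 18300 probes of all kinds were called lower and 9448 higher, against 12899 and 9405 with it. The 75th percentile used for scaling was 1092 to 1605 on the linalool arrays and 849.6 to 999.6 on the mock arrays. An equal signal near background therefore comes out lower on the linalool arrays, so the added calls need not mean lower expression. Whether low signal accounts for the excess of lower microRNA probes was not tested.

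Tested genes that are neighbours in the order of locus numbers differed between the groups in a weakly shared direction. Over 21532 such pairs, which are pairs of genes and not independent replicates, Spearman's correlation was 0.071, against at most 0.026 in 1000 shuffles of locus order. Without pairs in which both genes changed at least 4-fold, it was 0.055 against at most 0.022. That step left out 352 pairs and does not pick out tandem copies, so although it had been planned as their test, it decides nothing, and tandem copies read by 1 probe stay open.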
